A study of Mus musculus with 2 samples.

How the data were processed

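Single-cell RNA sequencing was carried out on livers of Kunming mice, an outbred stock, aged 6 to 8 weeks per the labels. Mice received saline or 200 mg/kg of bavachin, a flavonoid found in the fruit of Psoralea corylifolia, and both groups have a time of 7 days in the labels, which give no sex. Per the labels' protocols, livers were perfused with collagenase, hepatocytes were parted from the other cells by centrifugation at 50 g, cells of several mice per group were pooled in equal amounts, and dead cells were removed from each fraction. Per the labels, libraries were made with the 10x Genomics 3′ version 3 kit. Each group is therefore 1 library made from a pool of mice, and the labels do not tie cells to mice.

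Per the labels, reads were processed with Cell Ranger against mm10, with no version of the tool or the annotation stated. The deposited values are a score per cell and gene, and each table also gives the authors' cell type label for every cell. No label or header describes how the score was made. The values themselves show its form: the UMI (unique molecular identifier) count over the cell's total, times 10000, plus 1, on the natural log scale, then centred and divided by the gene's standard deviation, with an upper limit of 10. The lowest values of genes seen in 1 cell place the number of cells in that scaling at 23591, of which 8540 are not in the tables used here. The 15051 cells of the tables have at least 494 detected genes and at most 50.0% mitochondrial transcripts.

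Whole UMI counts were recovered from the scores by inverting these steps. Of 15902 gene columns 11887 could be inverted, and they hold 99.6% of all values above a gene's lowest value. Of the inverted values 100% were whole numbers within a tolerance of 0.01. No gene left out was detected in more than 75 cells. A value at the upper limit, 2.18% of those above the lowest, was counted as the smallest count that reaches the limit, so sums of genes seen in few cells are lower bounds where many of their values lie there. The recovery was tested on simulated data of 2500 cells and 1997 genes. There 1904 genes were inverted, and 100% of their counts above 0 and below the upper limit were right. Counts at the limit were not scored.

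The cell classes are the 10 deposited labels. Clusters had been planned because no annotation was listed, and they serve as an alternative. Clusters were made with scanpy 1.11.5 and leidenalg 0.10.2 over both libraries without integration (2000 variable genes, 30 principal components, 15 neighbours, resolution 1, seed 0). They were named from 15 marker lists, and unnamed clusters rich in hepatocyte markers were called hepatocytes, a step that was not in the plan. No doublet caller was run. Cells that detect at least 3 markers of each of 2 classes were treated as possible doublets and left out in an alternative. In cells not labelled Hepa, hepatocyte markers were not counted for this, so the alternative does not address doublets of these cells with hepatocytes.

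Counts were summed per class and library and given as CPM, the usual scaling of UMI counts to a fixed class total. Shares of cells carry exact Clopper-Pearson 95% intervals, and CPM ratios carry exact Poisson-based 95% intervals of the counts. All these intervals cover counting error only, not the difference between mice or preparations. With 1 library per group no test was run and no p-value is given. A gene met the size rule when it was detected in at least 10% of the cells of a class in either library and its CPM differed at least 2-fold. Against 0 counts a ratio was taken to a floor of 3 counts per library. The rule was tested on simulated data for the hepatocyte comparison of 1823 genes, with genes made higher or lower. It called 0% of 50 genes changed 1.5-fold, 100% of 50 changed 2.5-fold and 0% of the unchanged genes. Of the intervals 95.0% held the true ratio.

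In each class 37 gene lists were summarised by the median log2 CPM ratio of their members that passed the detection filter. Lists with fewer than 3 such members have no median. Each median has a percentile among 10000 random lists of the same size matched on mean level in 20 bins, which describes these libraries and is no test. In the same simulation 2% of 200 unchanged lists fell outside the percentiles 2.5 to 97.5, and 100% of 50 changed lists lay above the upper one.

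The size rule, lists, markers, most of the alternative settings and rule for named genes were fixed before the data were examined. The named genes are the 12 largest increases and 12 largest decreases in hepatocytes, the 6 in each direction in other classes with at least 200 cells in both libraries, 8 hepatocyte genes named in advance, and the members with the largest differences of each list described, and not all of these are reported here. Gene models, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes and markers of other classes were not ranked. Outside hepatocytes, genes detected in more hepatocytes than cells of the class in both libraries were not ranked either, because such transcripts can be free hepatocyte RNA. This rule took the T and EC labels. The lists described at length were picked after their medians had been computed.

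Alternatives changed 1 choice at a time, except that the measure and its size changed together: the classes (clusters at resolutions 0.5, 1 and 2, or the class with the highest marker score), the cells (without possible doublets, or without the 20% of cells with the fewest detected genes), the detection filter (none, or 25%), the size (3-fold, or 1.33-fold), the measure (share of cells with the gene, with a difference of 20 percentage points as the size), the depth (cells thinned to 1000 UMIs) and the weights (equal numbers of cells from each cluster). After seeing the data, clusters at resolution 1, CPM without mitochondrial transcripts and Lars2, and CPM over genes detected in more cells of a class than of hepatocytes were added, as were random lists matched also on a predicted signal peptide or membrane span. That prediction was made from the hydropathy of translated coding sequences of GENCODE vM21, not with a dedicated tool. Gene positions come from GENCODE vM21 (GRCm38, the assembly of mm10). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.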

Results

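Liver cells of mice given saline or bavachin were profiled to compare healthy with bavachin-treated livers. The saline control library holds 7863 cells and 25830418 UMIs, with a median of 2473 per cell, and the bavachin library holds 7188 cells and 14255953 UMIs, with a median of 1741. Each group is 1 library from a pool of mice, so every difference given here compares these libraries and the difference has no replicate check. Ratios are CPM in bavachin over control, on the log2 scale with a 95% counting interval in parentheses where one is given. Positions are on GRCm38.

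The makeup of the libraries differed among the cells that are not hepatocytes, of which 2642 were in control and 1441 in bavachin. Cells labelled EC made up 16.7% (15.3 to 18.2) of these in control and 45.2% (42.6 to 47.8) in bavachin, while cells labelled SEC made up 26.3% (24.7 to 28.1) and 9.58% (8.11 to 11.2). Cells of both labels carry endothelial markers, and together they made up 43.0% in control and 54.8% in bavachin. Cells labelled T made up 29.6% (27.9 to 31.4) and 20.5% (18.5 to 22.7). Cells labelled B, which carry B cell markers, were at 11.1% and 11.5%.

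Among the smaller labels, NK was at 5.30% and 3.61%, Mo/MoMF at 3.63% and 2.57%, DC at 3.44% and 1.94%, HSC at 2.04% and 3.12%, and KC at 1.85% and 1.94%. Cells labelled Hepa, the hepatocytes, were 66.4% (65.3 to 67.4) of all cells in control and 80.0% (79.0 to 80.9) in bavachin. Hepatocytes and other cells were separated before loading, a step that can change this share. When each cell took the class with its highest marker score, 15.8% and 47.9% were hepatocytes, and the cells of both endothelial labels became 12.7% and 8.93% of non-hepatocytes, with T at 8.53% and 5.34% and B at 4.76% and 4.57%. Of the settings tried, only this one put the joint endothelial share lower in bavachin.

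The line between EC and SEC went with depth and with the detection of endothelial markers. SEC-labelled cells had a median of 6782 UMIs in control and 2008 in bavachin, and EC-labelled cells had 2046 and 1641. The 12 endothelial markers were detected in a mean of 95.5% of SEC cells in control and 60.1% in bavachin, and in 46.3% and 29.6% of EC cells. In hepatocytes, which should lack them, the means were 1.34% and 1.41% at median depths of 2132 and 1710 UMIs. Thinned to 1000 UMIs per cell, with no cell left out, the endothelial markers were found in a mean of 70.0% and 41.4% of SEC cells and in 30.7% and 20.9% of EC cells. In clusters made without the labels, 94.8% of control SEC cells lay in cluster 7, and 71.7% of bavachin SEC cells lay in cluster 4, which also held 89.3% and 85.4% of the EC cells.

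**Figure D1:**
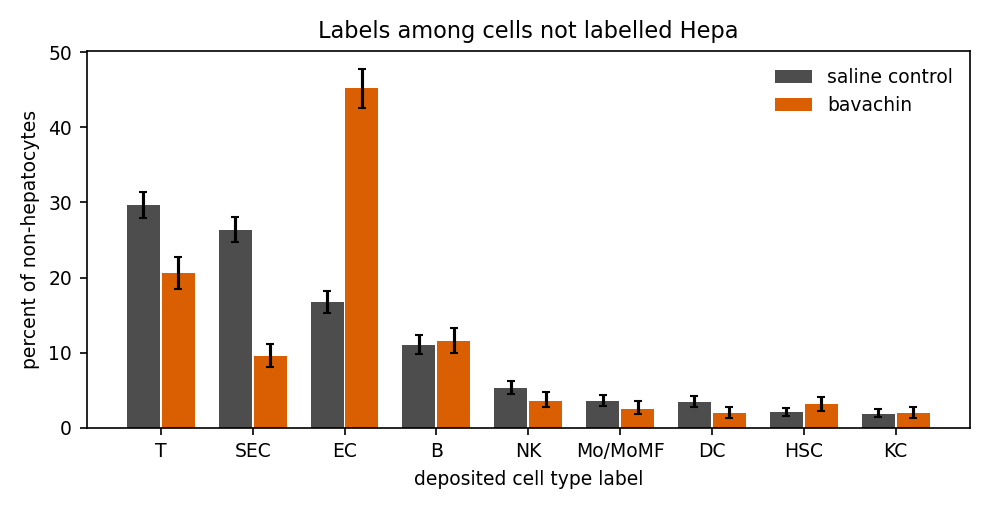
Share of each deposited label among cells not labelled Hepa, in percent, for saline control (grey) and bavachin (orange); bars are shares and error bars are 95% Clopper-Pearson intervals. The EC bar stands at 16.7% in control and 45.2% in bavachin, and the SEC bar at 26.3% and 9.58%.

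Hepatocyte transcripts were present in every other class, at a higher level in bavachin. The median level of the 12 hepatocyte markers, as a percent of that in hepatocytes of the same library, was 18.4% in control T cells and 39.4% in bavachin T cells. It was 54.0% and 82.2% in EC, 11.6% and 51.1% in SEC, 17.9% and 44.2% in B, and 16.5% and 64.4% in KC. Thinned to 1000 UMIs per cell, with 1 bavachin T cell left out, these markers were detected in a mean of 39.4% of T cells in control and 69.1% in bavachin.

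**Figure D2:**
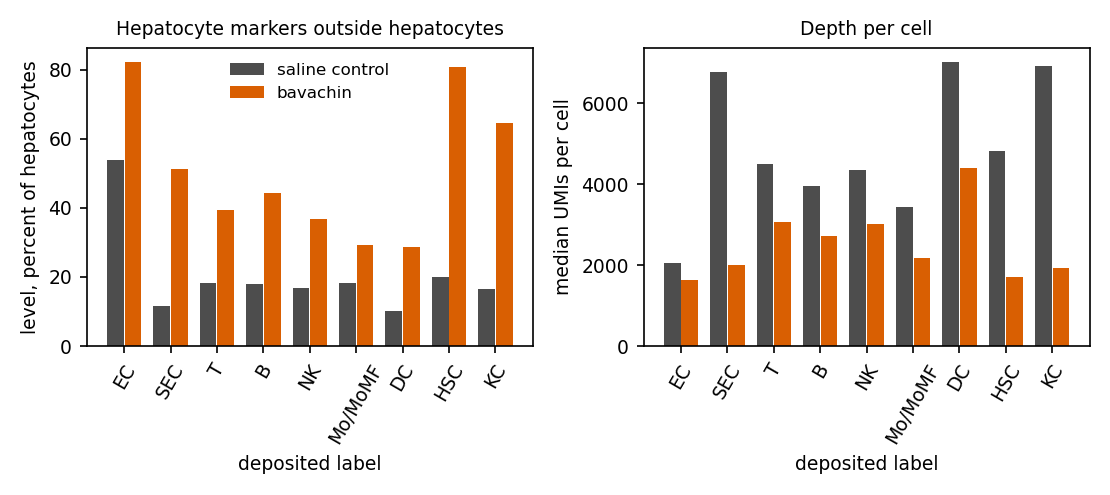
Left, median level of 12 hepatocyte markers in each other label as a percent of the level in hepatocytes of the same library; right, median UMIs per cell of the same labels, with control in grey and bavachin in orange. In T cells the marker level is 18.4% in control and 39.4% in bavachin, with median depths of 4493 and 3067 UMIs.

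In hepatocytes, acute phase, coagulation, complement and cytochrome P450 genes stood higher in bavachin, while Gstp1, Gsta3, Elovl3, Mup21, Mup7 and Mup20 stood lower. The acute phase list, plasma proteins the liver makes in inflammation, had a median of 1.23 with all 19 measured members above 0. The 13 measured drug-metabolising P450 genes had a median of 0.98. The list of major urinary proteins and sex-biased genes had a median of -0.75 over 10 members. Of 1823 genes tested, 5.595% met the size rule as higher and 0.823% as lower, at a median over all genes of -0.12.

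The largest ranked increase, among genes detected in at least 10% of hepatocytes of either library, was in Cyp2c40 (chromosome 19, 39767071 to 39812814), a P450 known as female-biased in mouse liver, with 16 UMIs in control and 811 in bavachin, or 1.28 and 75.8 CPM, a log2 ratio of 5.88 (5.18 to 6.70). Lars2 (chromosome 9, 123366927 to 123462666), the mitochondrial leucyl-tRNA synthetase, was at 882 and 6673 CPM, a ratio of 2.92 (2.89 to 2.95). Hao2 (chromosome 3, 98874521 to 98893239), a peroxisomal hydroxyacid oxidase, was at 14.7 and 78.3 CPM, a ratio of 2.41 (2.18 to 2.65). B2m, the light chain of class I MHC (chromosome 2, 122147686 to 122153083), was at 250.3 and 935 CPM, with a log2 ratio between 1.84 and 1.96 within counting error. Wfdc21 had a ratio of 1.81, the fibrinogen chain Fga 1.79, the glutamine transporter Slc38a3 1.61, the desaturase Scd1 1.58, Cyp4f14 1.57, G6pc, the last step of glucose output, 1.55, and the pentraxin Apcs 1.53.

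Pde4d (chromosome 13, 108449948 to 109953461), a cAMP phosphodiesterase, had the largest ranked decrease, at 244 CPM in control and 30.5 in bavachin, with a log2 ratio between -3.17 and -2.84 within counting error. Elovl3 (chromosome 19, 46131897 to 46135694), a fatty acid elongase known as male-biased in mouse liver, was at 177 and 22.4 CPM, a ratio of -2.98 (-3.18 to -2.79). Gstp1 (chromosome 19, 4035407 to 4037985), a glutathione transferase, was at 2502 and 675 CPM, a ratio of -1.89 (-1.93 to -1.85). Car3, a carbonic anhydrase and among the most abundant of these transcripts, was at 10562 and 4402 CPM, a ratio of -1.26. The other large decreases were in Echdc2 (-2.10), Tstd1 (-1.93), Mup21 (-1.89), Mup7 (-1.77), Selenbp2 (-1.73), Traf5 (-1.64), Mup20 (-1.11) and Ppdpf (-1.03). Reads of the Mup, Cyp2c and Gstp families can be shared between near-identical copies, so the member named is uncertain.

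**Figure D3:**
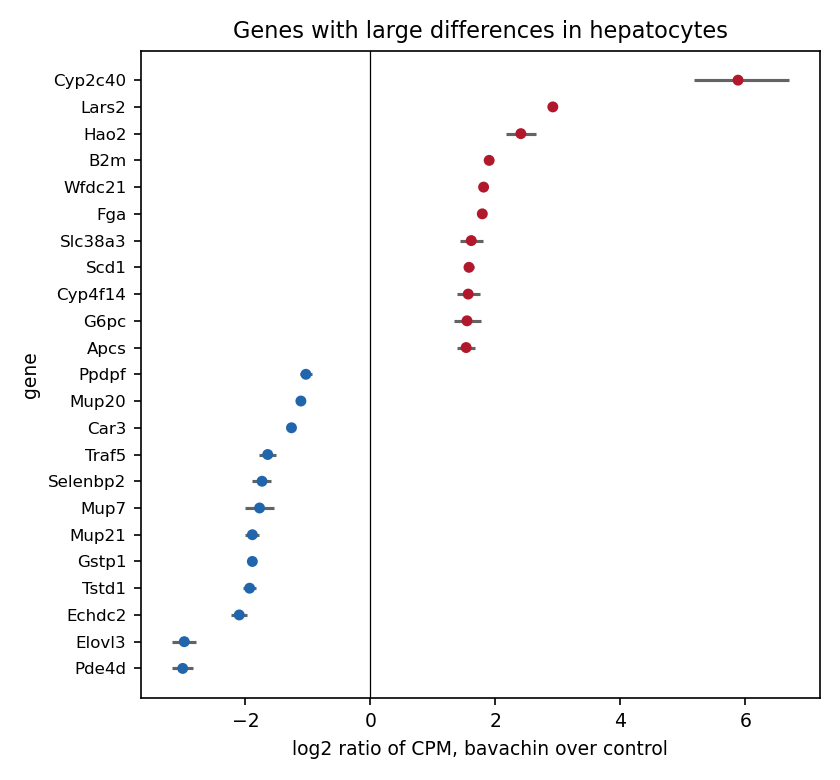
Log2 ratio of CPM, bavachin over control, in hepatocyte-labelled cells for the genes named among the largest increases (red) and decreases (blue); horizontal bars are 95% counting intervals. The lowest value is that of Pde4d, with an interval of -3.17 to -2.84, and the highest is 5.88 for Cyp2c40.

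Of the acute phase list 13 of 19 members met the size rule as higher, with Fga at 1.79, Apcs at 1.53, Serpina3n at 1.48 and Hamp2 at 1.47, and the metallothionein Mt1 at 0.28 as its lowest value. Its median stood at the percentile 100 of random lists. The coagulation and complement list had a median of 0.94 (percentile 100) with 7 of 17 members higher, among them C3 at 1.33 and Serpind1 at 1.19. The P450 list (percentile 100) had 6 of 13 members higher, with Cyp3a11 at 1.45, Cyp2f2 at 1.44 and Cyp2d10 at 1.28. The list of bile acid and organic ion transport had a median of 1.15 (percentile 99.9) over 4 members, and both Slc10a1 and Slco1b2, uptake carriers for bile acids and organic anions, were higher at 1.32. The list of the unfolded protein response in the endoplasmic reticulum had a median of 0.81 (percentile 99.9), and 2 of 9 members, the chaperones Canx at 1.04 and Hspa5 at 1.02, were higher. Fatty acid and triglyceride synthesis had a median of 0.75 (percentile 99.9) with 3 of 7 members higher, namely Scd1 at 1.58, Elovl5 at 1.26 and Dgat2 at 1.14, while Thrsp was at -0.45.

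Most of the higher lists consist mainly of transcripts whose protein has a predicted signal peptide or membrane span, a class with a median of 0.65 in hepatocytes against -0.18 for the others. By this prediction the class holds all 13 measured P450 members, all 4 of transport and 16 of 19 of acute phase. It also holds 14 of 17 of coagulation and complement and 8 of 9 of the unfolded protein response. For fatty acid and triglyceride synthesis it holds 2 of 7. The prediction misses some members, as the fibrinogen chain Fga, a secreted protein, was placed outside the class. These counts, also that of fatty acid and triglyceride synthesis, may therefore be too low. Random lists were also matched on level and on this class, an alternative chosen after seeing the data. The percentile was then 100 for acute phase, 99.5 for coagulation and complement and 99.9 for fatty acid and triglyceride synthesis. It was 96.2 for P450, 93.3 for transport and 91.3 for the unfolded protein response. Missed members such as Fga are matched to genes outside the class, which stand lower, so these percentiles may be too high. The 3 coagulation and complement members outside the class had a median of 0.89, near the 0.94 of the 14 within. The percentiles therefore do not show that a list exceeds the class.

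The list of conjugation enzymes and glutathione transferases had a median of -0.40 (percentile 0.02) over 17 members, with 4 predicted members at 0.74 and 13 others at -0.53. Gstp1 at -1.89 and Gsta3 at -1.02 met the size rule as lower, and the glucuronosyltransferase Ugt2b5 met it as higher at 1.09. In the list of major urinary proteins and sex-biased genes (percentile 0) 4 of 10 members were lower, Elovl3, Mup21, Mup7 and Mup20, while Mup3 was at 0.69 and Slco1a1 at 0.94. The macrophage list named after lipid and scars had 4 members measured in hepatocytes, with a median of 1.24 (percentile 99.98), and 3 were higher, the fatty acid binding protein Fabp5 at 1.48 and the cathepsins Ctsb at 1.43 and Ctsl at 1.06. The pericentral zone list had a median of 0.22 (percentile 97.2) with no member past the rule, and the periportal zone list had 0.33 (percentile 98.6) with 2 of 12 higher, Cyp2f2 at 1.44 and Apof at 1.05.

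The other lists with a median lay between -0.52 and 0.20. Bile acid synthesis was at -0.31 (percentile 4.04), with Slc27a5 as its 1 higher member at 1.35, the targets of NRF2, a regulator of antioxidant genes, at -0.27 (4.69), cholesterol synthesis and uptake at -0.28 (9.57), and fatty acid oxidation at -0.22 (8.46). The urea cycle list was at -0.21 (7.66), mitochondrially encoded transcripts at -0.23 (3.62), the respiratory chain at -0.09 (21.1), heat shock at -0.07 (47.8) and ferroptosis and iron handling at -0.08 (40.5). Gluconeogenesis was at 0.04 (90.5), interferon response at 0.20 (84.3), ribosomal proteins at 0.17 (88.6), the integrated stress response at -0.46 (11.2) over 3 members, and growth and progenitor genes at -0.52 (1.12) over 3. Hamp, the iron hormone hepcidin, at 1.28, G6pc at 1.55 and Bst2 of the interferon list at 1.60 were the only members of their lists past the rule. The integrated stress response, heat shock, NRF2, respiratory chain, urea cycle, pericentral, ribosomal, mitochondrial, fatty acid oxidation and growth lists had no member past the rule. Of the other 12 lists, those of p53 targets, MHC class II, sinusoidal and stellate genes, cytotoxicity, T cell activation and neutrophils had 0 measured members in hepatocytes, and those of immediate early genes, cell cycle, cytokines, Kupffer cells and endothelial activation had 1 or 2.

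**Figure D4:**
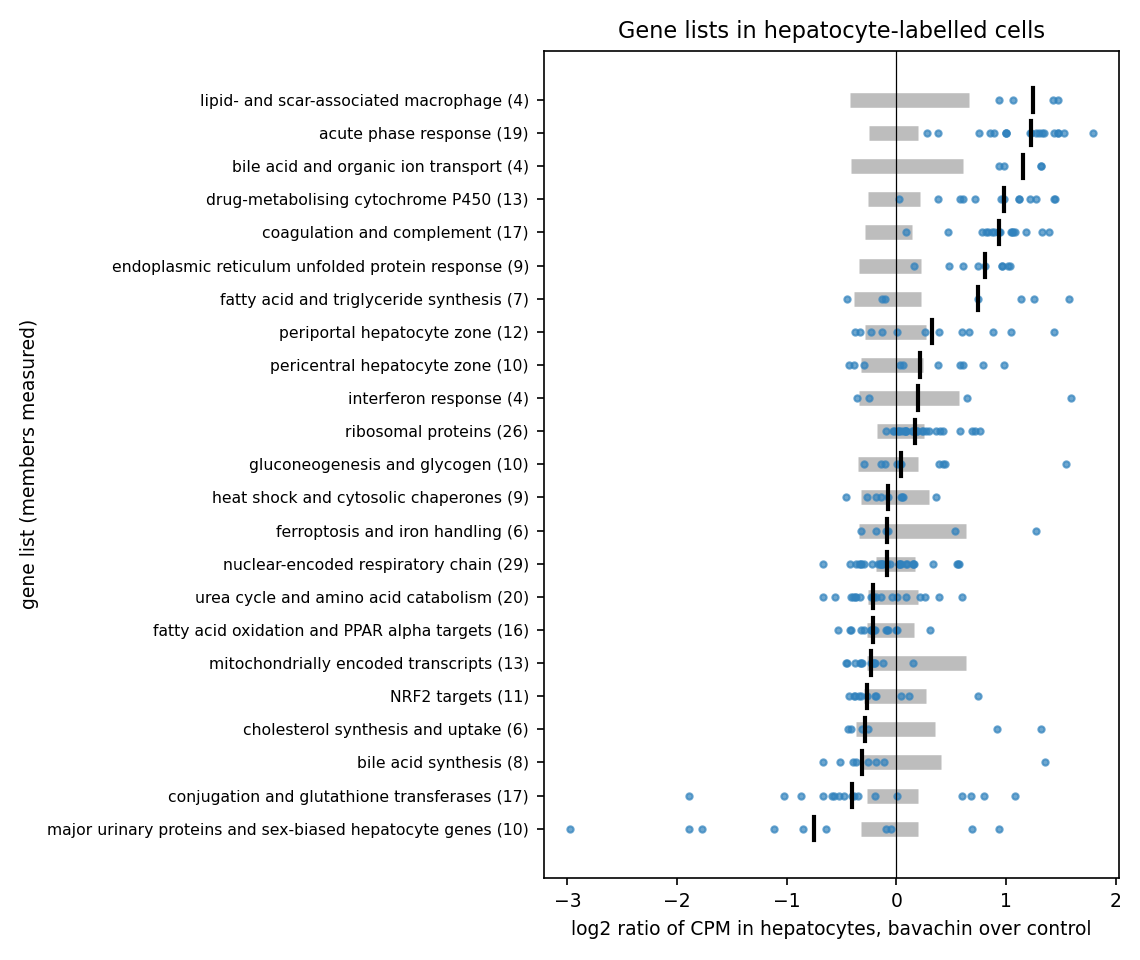
Log2 ratio of CPM, bavachin over control, in hepatocyte-labelled cells for the measured members (blue points) of lists with at least 4 of them, with the list median (black line) and the central 95% of medians of random lists matched on level (grey band). The acute phase median of 1.23 and the P450 median of 0.98 lie above their bands, and the median of -0.75 for major urinary proteins and sex-biased genes lies below.

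Of the genes named in advance, Abcb11, the bile salt export pump, was at 15.9 and 56.4 CPM, a ratio of 1.82 (1.59 to 2.06), but was detected in under 10% of cells. Slc10a1 was at 55.1 and 138 CPM, a ratio of 1.32 (1.19 to 1.45), Cyp3a11 at 432 and 1179 CPM, a ratio of 1.45 (1.40 to 1.49), Cyp2e1 at 0.58 and Gpx4 at -0.09. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 36 and 38 UMIs, a ratio of 0.30 (-0.40 to 1.00), Nqo1 had 40 and 37 UMIs at 0.11 (-0.58 to 0.79), and Hmox1 had 21 and 28 UMIs at 0.64 (-0.23 to 1.53). A difference in these 3 genes was not detectable at this depth, and 81.1%, 85.7% and 83.7% of their values lie at the upper limit of the deposited score.

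Hepatocytes of the libraries fell into different clusters. Cluster 0 held 128 control and 3226 bavachin hepatocytes and cluster 3 held 90 and 1123, while cluster 1 held 2799 and 132 and cluster 2 held 1370 and 48. Clusters 5 and 6 held 270 and 519 control and 749 and 385 bavachin hepatocytes. A cluster mostly of 1 library may be that library and not a type. Mitochondrial transcripts made up a median of 37.5% of UMIs in control hepatocytes and 29.0% in bavachin. Without them and Lars2 in the total, the median over all genes moved from -0.12 to -0.22 in hepatocytes, from -0.15 to -0.21 in T cells and from -0.12 to -0.26 in EC, and the gluconeogenesis list went to -0.07. With equal numbers of cells from each cluster, P450 fell to 0.36, the transport list to 0.44, the unfolded protein response to 0.31, coagulation and complement to 0.42 and acute phase to 0.73, and the genes past the rule as higher numbered 16 (59 with classes by marker score). With equal cells the fatty acid oxidation list stood at 0.04 and the list of NRF2 targets at 0.03, and Gpx4 at 0.14 and Nqo1 at -0.03 also took the other sign.

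In T-labelled cells, the medians of the cytotoxicity and activation lists lay below 0, with few members past the size rule, and hepatocyte transcripts stood higher in bavachin. The cytotoxicity list had a median of -0.59 over 17 members (percentile 0), none above 0 and none past the size rule, with the chemokines Ccl4 at -0.98 and Xcl1 at -0.95 and the cystatin Cst7 at -0.82. The list of activation and exhaustion had a median of -0.53 over 12 members (percentile 0), of which Cd69, an early activation marker, was lower at -1.16 and the naive and memory cell factor Tcf7 was at -0.77. A larger share of hepatocyte RNA in bavachin lowers the CPM of T cell genes. With CPM taken over genes detected in more T cells than hepatocytes, the cytotoxicity median was -0.51 and the activation median -0.45. The cytotoxicity difference did not hold without possible doublets, a rule that also removes cells with both T and NK markers, where its median was 0.083.

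The T label spans 3 clusters: cluster 9 (298 control and 113 bavachin cells, led by Lef1, Tcf7 and Il7r), cluster 10 (231 and 100, led by Cxcr6) and cluster 11 (248 and 80, led by Klra5 and Xcl1), which carries more NK than T markers among its leading genes. The cytotoxicity median was -0.04 over 4 members in cluster 9, -0.49 over 17 in cluster 10 and -0.63 over 16 in cluster 11. The activation median was -0.64, -0.40 and -0.92 in clusters 9, 10 and 11. Immediate early genes, which dissociation can induce, had a median of -0.41 (percentile 0.29) in T cells and of -0.29, -0.34 and -0.66 in these clusters. The cytokine list had a median of -0.55 (percentile 1.87) over 5 members, with Tnf lower at -1.20, and was at 0.84, -1.13 and -0.63 in these clusters. Its median stood above 0 with classes by marker score (0.10), without possible doublets (0.12) and with no detection filter (0.35).

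Of 5287 genes tested in T cells 290 met the size rule as higher and 85 as lower. Among the 4662 detected in more T cells than hepatocytes in either library, 51 were higher and 84 lower, so most of the higher genes were transcripts more common in hepatocytes. The acute phase list, for example, was at 1.75 in T cells and at 2.04, 1.67 and 1.98 in clusters 9, 10 and 11. The largest ranked increase was in Tnr (chromosome 1, 159523769 to 159931729), which encodes the matrix protein tenascin R, with 15 and 158 UMIs, or 3.95 and 159 CPM, a ratio of 5.33 (4.57 to 6.20), and with 4.57 in cluster 9 and 4.34 in cluster 10. Cyp2c54 at 3.32, Slc38a3 and Cyp4f14 at 2.21 and Ugt2b34 at 2.05 are hepatocyte genes, and Lars2 was at 2.17.

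The largest ranked decrease in T cells was in Gdpd3 (chromosome 7, 126766334 to 126775649), a phosphodiesterase gene, with 141 UMIs in control and 1 in bavachin, a ratio of -5.21 (-10.52 to -2.70), and 30.2% of its values lie at the upper limit of the score. Cpm, a carboxypeptidase, had 131 and 4 UMIs, a ratio of -3.10 (-5.00 to -1.71), and 10.3% of its values lie at that limit. Slfn1, a schlafen gene of quiescent T cells, was at -2.09 with 28.3% of its values at that limit, Tpm3-rs7 at -2.08, the sialyltransferase St8sia6 at -1.92 with 42.9% at the limit, and Rnaset2a at -1.78. With cells thinned to 1000 UMIs, 26 genes were lower and 172 higher, and with the clusters in place of the labels 133 were lower.

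In EC-labelled cells, genes of sinusoidal endothelium stood lower in bavachin. With EC and SEC cells together, where 57.2% of all genes were lower, the sinusoidal identity list had a median of -2.19 with all 19 measured members lower. The label mix behind this pooled ratio changed: SEC cells held 4774200 of 5797214 UMIs in control and 313936 of 1451528 in bavachin. Pooled ratios therefore also take up the shift between labels. In SEC alone, where 38.5% of genes were lower, this list had a median of -1.27 with 16 of 20 lower. In EC alone it had a median of -0.89 over 14 members, none above 0 (percentile 0), and 5 were lower: the growth factor Bmp2 at -1.74 (509 and 153 CPM), the Wnt agonist Rspo3 at -1.53, the receptor Kit at -1.51, the ligand Wnt2 at -1.16 and Oit3 at -1.02. Over genes detected in more EC cells than hepatocytes in either library the median ratio was -0.48, beside hepatocyte markers at 54.0% and 82.2% of their hepatocyte level. A larger share of hepatocyte RNA lowers the CPM of endothelial genes. Random lists drew on all tested genes, so the percentiles of endothelial lists do not part a change in these cells from such dilution. With CPM taken over the genes detected in more EC cells than hepatocytes, the sinusoidal median was -0.72. Of the list of activation and capillarisation, with a median of -1.06 over 5 members (percentile 2.11), Plvap, a component of capillary diaphragms, was lower at -2.66, Nos3 at -1.07 and the shear-responsive factor Klf2 at -1.06, and Lrg1, which hepatocytes also express, was higher at 1.16. The stellate and matrix list was at -0.75 over 4 members (percentile 1.52). Immediate early genes, which dissociation can induce, had a median of -1.06 in EC with 2 of 3 members lower (percentile 0.74). Klf2 is in this list and in that of activation and capillarisation. Both EC medians are its value, so they are not separate results. In EC and SEC cells together the immediate early list was at -3.12 with all 17 lower (percentile 0), a pooled ratio with the same limit as above.

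Of 2170 genes tested in EC cells 166 met the size rule as higher and 171 as lower, and of the 1137 detected in more EC cells than hepatocytes in either library 1.76% were higher and 14.3% lower. Ranked increases included Lars2 at 2.79, the kininogen Kng2 at 1.73, C4bp at 1.44, Apoc1 at 1.43 and Prdx4 at 1.39, and the acute phase list was at 1.57 and P450 at 1.43. Hepatocytes carry these transcripts too: Apoc1 was detected in 100% of hepatocytes of both libraries, and C4bp in 13.9% in control and 22.4% in bavachin. These increases can therefore be hepatocyte RNA. The ranked decreases were Tpm3-rs7 at -4.32 (-5.98 to -3.05), with 90 and 5 UMIs, Plvap (chromosome 8, 71497765 to 71511752) at -2.66 (-3.68 to -1.76), with 66.5 and 10.5 CPM, Pde4d at -2.60, Fcer1g at -2.57, Rcn3 at -2.42 and Slc44a2 at -2.40. With cells thinned to 1000 UMIs 49 genes were lower, and without mitochondrial transcripts and Lars2 in the total 259 were.

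Of 1423 genes tested in all 3 classes, 62 were higher and 3 lower in each of hepatocytes, T and EC. No gene met the rule in opposite directions in any pair of these classes, over 1586 genes shared by hepatocytes and T, 1507 by hepatocytes and EC, and 1859 by T and EC. Since hepatocyte RNA is present in both other classes, these counts do not show that T or EC cells make the same transcripts.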

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

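Of the alternatives in this part, clusters at resolution 1, CPM without mitochondrial transcripts and Lars2, and CPM over genes detected in more cells of a class than of hepatocytes were chosen after seeing the data; the others were planned. The size and filter settings leave a gene's ratio unchanged, so their values keep the sign by construction. Most named genes were also picked as the largest differences in these libraries. With all of these counted, 755 of 760 values of the 56 named genes over 15 alternatives kept their sign. The exceptions are Nqo1 at -0.34 with classes by marker score, -0.12 by share of cells and -0.03 with equal cells per cluster, Cyp7a1 at -0.03 by share of cells, and Gpx4 at 0.14 with equal cells per cluster. Of the values that answer a comparison, 173 stayed within the set tolerance, 79 moved and 1 reversed, and of the other values 1402 stayed, 239 moved and 7 reversed. Ratios of named genes under the size and filter settings are among the 1402. Lists with under 6 members had a tolerance of 0.5 on the log2 scale. Leaving out the 20% of cells with the fewest detected genes moved none of the main results. The EC and SEC labels have no value of their own under clusters or marker scores, where cells of both are named endothelial. No paired analysis was possible because each group is 1 library and the results come from no test. Where construction does not show it, the cause was not tested.

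The size and the filter set the counts by construction. With a 3-fold size, 9 genes were higher in hepatocytes, 81 in T and 42 in EC, and 9 were lower in T and 21 in EC. With a 1.33-fold size, 307 were higher and 254 lower in hepatocytes, 723 and 1173 in T, and 386 and 697 in EC. With detection in 25% of cells, 53 were higher in hepatocytes, 139 in T and 82 in EC, and 8 were lower in T and 33 in EC. With no detection filter, 1275 were higher and 435 lower in hepatocytes, 1474 and 575 in T, and 1068 and 2159 in EC. The cytokine list in T then stood at 0.35 and the list of endothelial activation in T at 0.93, both reversed by members seen in few cells.

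Depth and scaling moved counts of genes too. With cells thinned to 1000 UMIs, 172 genes were higher and 26 lower in T, the cytotoxicity median in T was -0.74, and 49 genes were lower in EC. Over a class's own genes, 56 were lower in T and 103 in EC. Without mitochondrial transcripts and Lars2, 259 were lower in EC and the coagulation and complement median in hepatocytes was 0.83. By share of cells, where the measure and its size (20 percentage points) change together, 14 genes were higher in hepatocytes, 65 higher and 147 lower in T, and 25 higher and 25 lower in EC. The ribosomal list in hepatocytes went to -0.83 points and the respiratory chain list in T to -0.11 points, both reversed. Shares fall with depth, which was lower in bavachin.

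With equal cells from each cluster, each cluster that is mostly of 1 library gives few cells of that library, so differences between clusters shrink by construction. There were 16 genes higher in hepatocytes, and medians there were 0.73 for acute phase, 0.36 for P450, 0.44 for transport, 0.31 for the unfolded protein response and 0.42 for coagulation and complement, with fatty acid oxidation reversed at 0.039.

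With clusters at resolution 0.5, hepatocytes were 81.7% of bavachin cells, T cells 18.1% of control and 13.1% of bavachin non-hepatocytes, 158 genes were lower in T and the cytotoxicity median was -0.46. At resolution 1 hepatocytes were 81.2% of bavachin cells, T cells 20.4% and 15.9%, 133 genes were lower in T and the cytotoxicity median was -0.34. At resolution 2, T cells were 20.4% and 15.3%, EC and SEC together 50.8% of bavachin non-hepatocytes, 131 genes were lower in T and the cytotoxicity median was -0.37. In these settings cells of the cluster with NK-type markers leave the T class.

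With classes by marker score, hepatocytes were 15.8% of control and 47.9% of bavachin cells, and of non-hepatocytes EC and SEC together were 12.7% and 8.93%, T 8.53% and 5.34%, and B 4.76% and 4.57%. Then 59 genes were higher in hepatocytes and 129 lower in T, the coagulation and complement median in hepatocytes was 0.73, the cytotoxicity median in T was -0.33 and the cytokine list in T reversed to 0.10.

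Without possible doublets (945 control and 205 bavachin cells), hepatocytes were 74.8% and 81.8% of cells. Of non-hepatocytes EC were 23.9% and 50.4%, EC and SEC together 49.2% and 60.6%, T 22.5% and 15.5%, and B 13.4% and 12.2%. In T, 149 genes were lower, the activation median was -0.73, and the cytotoxicity median at 0.083 and the cytokine list at 0.12 reversed. Cells that carry both T and NK markers count as possible doublets under this rule, so it removes cytotoxic T cells too.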

Other observations

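The predicted class of transcripts, the sets of sex-biased genes and the split by T cluster were chosen after values had been seen, as were the test on hepatocyte transcripts in T cells and its limits, the tests on Y-linked transcripts for the male-biased genes, on single-copy genes, on the pair of Glul and Oat and on gene span; the tests on mitochondrial share, on the linear model, on Y-linked transcripts per cell and on joint detection were written before their results. The sex-biased sets were written from general knowledge of mouse liver when several of their genes had been seen.

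Classes under 200 cells in bavachin showed further groups of genes. In SEC-labelled cells, beside hepatocyte markers at 11.6% and 51.1% of their hepatocyte level and median depths of 6782 and 2008 UMIs, immediate early genes had a median of -2.63 with all 17 measured members lower, while 38.5% of all 7327 measured genes were lower, at a median of -0.77. The same list was at -2.32 in KC with 17 of 18 lower, at -2.36 in HSC with 13 of 16 lower and at -1.25 in Mo/MoMF with 10 of 16 lower, with medians over all genes of -0.09, -0.67 and -0.05 and hepatocyte markers at 16.5% and 64.4%, 19.9% and 80.7%, and 18.4% and 29.2%. Dissociation can induce these genes, and the cause of the difference was not tested. The makeup or depth of these classes differed too: endothelial markers were detected in a mean of 39.5% of control and 6.30% of bavachin HSC cells and stellate markers in 80.7% and 37.8%, monocyte markers in 39.5% and 10.7% of KC cells, and neutrophil markers in 15% and 3.78% and basophil or mast cell markers in 18.8% and 6.76% of Mo/MoMF cells. At resolution 2 a neutrophil cluster held 12 control and 0 bavachin cells, all labelled Mo/MoMF. The cell cycle list in Mo/MoMF, of 96 and 37 cells, was at 1.15 (-0.30 to 1.68) with 7 of 13 higher and 1 lower. In B cells, with hepatocyte markers at 17.9% and 44.2% of their hepatocyte level, the immediate early list was at -0.53 with none of 14 past the size rule, and the respiratory chain list was at 0.43 with none of 29 past it. In NK-labelled cells, with these markers at 16.8% and 36.8%, the cytotoxicity list was at -0.18 (percentile 12.35), with 4 of 17 members above 0. Cluster 15, led by Birc5 and Ube2c, genes of dividing cells, held 34 control and 65 bavachin hepatocytes.

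In hepatocytes, transcripts whose protein has a predicted signal peptide or membrane span stood higher in bavachin: 350 of them had a median of 0.65 and 1419 others one of -0.18, a gap of 0.833. Of the genes past the size rule as higher, 83.3% are predicted, against 19.8% of all. Matching hepatocytes on mitochondrial share left a gap of 0.879, although the mitochondrial and predicted shares correlated across cells (rho 0.268 in control, 0.375 in bavachin), and a linear model with length, GC content, span and level gave 0.699 where the means alone differ by 0.704, which argues against these as the whole cause. Loss of cytosolic RNA from damaged hepatocytes may leave RNA bound to the endoplasmic reticulum, and should then put the other transcripts into the free RNA; hepatocyte transcripts in T cells had a gap of 0.635 in the same direction, below the 0.858 of the same genes in hepatocytes, but whether they are free RNA or material of whole hepatocytes was not tested, so this loss stays open. Bavachin, the mice of each pool and the preparation of the control cells stay open too, since each differs between the libraries.

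A 2nd pattern in hepatocytes concerns sex-biased genes: 18 measured male-biased genes had a median of -0.52, with 13 below 0 and Slco1a1, Serpina12, Egfr, Cyp7b1 and Cyp2d9 above, and all 13 measured female-biased genes lay above 0, with a median of 5.31 that counts A1bg and Cyp4a14, at 0 UMIs in control, at their floor. The detection filter was not applied to these sets. Of the female-biased genes only Cyp2c40 and Hao2, each detected in 12.8% of bavachin hepatocytes, passed it. The male-biased genes Cyp4a12b, Cyp7b1, C6, Serpina12 and Cyp2u1 did not pass it. Female mice in the bavachin pool are a possible explanation of the pattern, but Y-linked transcripts had a ratio of 1.18 (1.06 to 1.31) in hepatocytes. In T cells it was 0.884 (0.745 to 1.04). Such sums cannot show a small share of female cells. Bavachin hepatocytes with a female-biased transcript held 1.102 (0.948 to 1.28) times the Y-linked level of the others. They were 47.3% of these cells, against 12.8% in control, so a small female group among them would be diluted. Pairs of female-biased genes were detected together 1.06 times (0.948 to 1.19) as often as by chance, though the pericentral pair of Glul and Oat also reached only 2.00, so that test could miss a group. Reads shared between paralogs are argued against by single-copy genes, also taken without the detection filter, whose female-biased minus male-biased median was 3.26. Bavachin and differences between outbred mice remain open and may each give such a shift. A small share of female cells also stays open for the female-biased genes.

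SEC-labelled cells made up less and EC-labelled cells more of the bavachin non-hepatocytes. RNA content of the droplet, more than cell type, may part the labels. Within control, the ratio of SEC over EC rose with gene span, with Spearman's rho of 0.489 across 4926 genes, which are not independent replicates. These were genes over 2-fold higher in SEC cells than in hepatocytes, so they were picked through the SEC side of the ratio. Their median log2 ratio was 1.27 for spans up to 19.1 kb and 2.45 for spans from 89.4 kb. Long spans go with unspliced nuclear RNA in 3′ libraries, so the labels may mark how much RNA a droplet kept. Hepatocyte RNA differed between the labels too: within control, hepatocyte markers stood at 54.0% of their hepatocyte level in EC and 11.6% in SEC. Thinned to 1000 UMIs per cell, these markers were found in a mean of 63.4% of control EC and 30.7% of control SEC cells. Whether hepatocyte RNA parts the labels was not tested. A change in endothelial cell state under bavachin was not tested and stays open.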
